A study of Homo sapiens with 18 samples.

How the data were processed

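Gene expression was measured on Affymetrix human exon arrays in 18 samples, comprising normal oviduct, serous tubal intraepithelial carcinoma (STIC) and invasive serous cancer from each of 6 patients. Per the labels' protocols, the tissues were collected by laser capture microdissection of frozen sections, total RNA was extracted with the PicoPure kit, and biotin was added with the Encore module. How the captured regions were recognised is not given in the sources used here.

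The deposited table held log2 values for 22011 gene-level features on each of the 18 arrays, with 0 missing values. The log base is not stated in the sources used here and was inferred from the deposited values, which ran from 0.70 to 13.55. The highest value lay above the natural log of the largest 16-bit intensity, 11.1, and below its log2, 16. Per the submitters' processing notes, the authors used Affymetrix Expression Console and Partek with the hg18 build. The tool versions, the summarisation of probes, the background correction and the normalization between arrays are not given in the sources used here. Medians of the arrays lay between 4.68 and 4.78, and no further normalization was applied.

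Features were named from the platform annotation, in which 14432 features had 1 gene symbol, 2408 had several and 5171 were not listed. Of the features with 1 gene, 14404 matched a reference gene table by gene ID, and 0 symbols changed. A total of 33 features of XIST and Y-linked genes were left out of every table. Features naming several genes or no gene were left out of the gene tests, and a gene with several features, as 197 genes had, was represented by the feature with the highest mean over the 18 arrays. This left 14223 genes, with no filter on dim genes. The sources used here give no detection call. The lower quartile of an array lay between 3.69 and 4.02, and 220 olfactory receptor genes averaged 3.43. A mean below 3.69 is therefore not shown to be above background, and a difference from it is a lower bound. MUC16 had no feature naming 1 gene and was not analysed here. The reference gene table follows GRCh38, so it gave only the chromosome and order of genes, and no coordinates are printed.

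The 18 arrays entered 1 linear model per gene with terms for tissue and patient, fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The patient was a block because the labels give 3 tissues for each patient number. Deviations from the tissue means correlated between same-patient arrays at 0.0360 to 0.315 for normal oviduct with STIC, 0.0410 to 0.305 for normal oviduct with invasive cancer, and 0.283 to 0.552 for STIC with invasive cancer. Tests were 2-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 14223 genes. Calls with a log2 difference of at least 1 in size were also counted. Residual and prior degrees of freedom together came to 15.7, and the number of arrays limits the precision: the median standard error of a difference was 0.16 on the log2 scale.

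The design, the tests, the alternatives, the gene lists and the rule for named genes were set before the data were examined. The rule took, per comparison, the 8 largest increases and 8 largest decreases among called genes with the same sign in all 6 patients. It added the 2 largest members of each list with at least 3 members called, in the direction most of them took, and a panel of 16 genes of the oviduct and of serous cancer. The 32 lists were written from general knowledge of the tissue and the disease, with no value from these arrays. The erythrocyte list, with 4 of 8 members measured, was under the minimum of 5 and was not tested. The other 31 lists were tested against all other genes with camera of limma at its preset correlation of 0.01, adjusted over the lists of a comparison. The results of 1 list and of 1 panel gene are not reported here, although the list enters the counts of lists. Members that rose or fell were counted with p adjusted over all genes and again adjusted over the list alone. For each list, an exact 2-sided sign-flip test on the 6 within-patient differences of the list mean was added, which cannot give a p below 0.03125.

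Alternatives were quantile normalization, centring of each array on its median, leaving out the dimmest 33.3% of genes, averaging features of a gene, testing every feature, array weights, trended and robust variance, no patient block, a random patient block, and only the 2 tissues compared. For lists they were camera with an estimated correlation and fry. Each patient was also left out in turn. Both comparisons with normal oviduct share its arrays, so the correlation of their differences was set beside 50 simulations of unchanged tissues and beside 20 splits of the patients into 3 and 3, and the overlap of their genes beside 10 of these simulations.

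The fit was tested on simulated data, in which 200 of 14223 genes were changed. For STIC against normal oviduct it recovered 19.4% of changes of 0.50, 79.1% of changes of 1 and 100% of changes of 2 on the log2 scale, and 4 of 136 calls were false. For invasive cancer against normal oviduct the shares were 23.9%, 85.1% and 98.5%, with 8 of 146 calls false. For invasive cancer against STIC they were 22.4%, 82.1% and 100%, with 9 of 145 calls false. Tables were prepared and figures drawn in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.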

Results

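The data were gene-level log2 expression values from 18 arrays, with 6 arrays each of normal oviduct (the Fallopian tube), STIC, which is a carcinoma confined to the tubal epithelium, and invasive serous cancer. Each of the 6 patients gave 1 array of every tissue, so each comparison was made within patients and the replicate number is the patient. The range between quartiles of an array lay between 1.53 and 1.94 on the log2 scale, and its median correlation with the other arrays between 0.862 and 0.931. Invasive cancer replicate 5 had the lowest values of both, 1.53 and 0.862, and STIC replicate 5 had the next lowest, 1.65 and 0.870.

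The comparison of STIC with normal oviduct asked which genes differ between the lesion and the normal tube of the same patient. Of 29 mitosis genes 19 rose in STIC, and of 33 motile cilia genes 28 fell. Camera of limma called both lists at its preset correlation but neither with an estimated correlation (adjusted p = 0.0633 for mitosis and 0.0788 for cilia). The other alternative for lists, fry, called both (fry adjusted p = 7.4e-04 and 9.76e-04). CRISP3 (feature 2956563), a secreted glycoprotein, fell by 5.52 ± 0.34 (SE) on the log2 scale, 46.0-fold, from 10.06 ± 0.39 to 4.53 ± 1.06 (SD, n = 6; limma adjusted p = 2.74e-07). STMN1 (feature 2402459), which encodes the microtubule regulator stathmin, rose by 2.11 ± 0.16 (SE), 4.32-fold, from 5.16 ± 0.35 to 7.26 ± 0.38 (SD, n = 6; limma adjusted p = 3.05e-06). CLDN6 (feature 3677350), a tight junction protein, rose by 3.20 ± 0.61 (SE), 9.16-fold (limma adjusted p = 0.00608). All 3 genes moved in the same direction in 6 of 6 patients. Averaged over all its features, STMN1 rose by 1.06.

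In STIC, the other named increases were H2AC21 at 2.07, H4C13 at 1.92, CCZ1P-OR7E38P at 1.90, MT1G at 1.88, FIGN at 1.78 and SSB at 1.73 on the log2 scale. H2AC21 and H4C13 are histone genes and MT1G is a metallothionein gene. These 2 histone genes, MT1G, CCZ1P-OR7E38P and SSB have near-identical copies or pseudogenes, so the source of their signal is uncertain. The named decreases after CRISP3 were AGR2 at -3.21, SCGB1A1 at -3.09, CDHR3 at -3.05, FYB2 at -2.98, CIMIP1 at -2.81, MS4A8 at -2.66 and FAM216B at -2.52. AGR2 is a protein disulfide isomerase of secretory cells, and SCGB1A1 is a secretoglobin of airway and other mucosal epithelia. The levels of AGR2, FYB2, CIMIP1 and FAM216B in STIC lay between 3.21 and 3.49, below the lower quartile of every array (3.69), so their decreases are lower bounds and have no order. The same holds for the decreases of RSPH1 and PGR in STIC, and for the increases of H4C13, CENPF and RBBP4, whose levels in normal oviduct lay between 3.49 and 3.59.

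Of 29 measured genes of the mitosis list, 19 rose in STIC and 0 fell (25 rose adjusted over the list alone). CENPF, a kinetochore protein, rose by 1.57, TPX2, a spindle protein, by 1.42, and the proliferation marker MKI67 by 1.30. The mean level of the mitosis list went from 3.91 ± 0.18 to 4.73 ± 0.19 (SD, n = 6), higher in 6 of 6 patients (camera of limma, adjusted p = 8.84e-23; adjusted p = 0.0633 with an estimated correlation). Of 26 DNA replication genes, 7 rose and 0 fell (11 rose adjusted over the list alone), among them GINS1 by 1.11 and RFC4 by 0.87. Of 21 homologous recombination and Fanconi anemia genes, 4 rose and 0 fell (9 rose adjusted over the list alone), with RAD54L at 1.17 and RAD51AP1 at 0.96. Among 16 polycomb and DNA methylation genes, 3 rose and 0 fell (4 rose adjusted over the list alone), with RBBP4 at 1.42 and DNMT3A at 0.58. Among 20 serous carcinoma reference genes, 3 rose and 0 fell (8 rose adjusted over the list alone): STMN1, the G1 cyclin gene CCNE1 at 1.05 (limma adjusted p = 0.00835) and the laminin gene LAMC1 at 0.87. The list medians were 0.42, 0.26, 0.25 and 0.37 in this order, and all 4 lists were called by camera with adjusted p of at most 0.00183. With an estimated correlation, adjusted p = 0.0633 for each of them. For the polycomb and DNA methylation list that correlation was -0.0121, below the preset 0.01, so its lost call does not show correlated members. With the dimmest 33.3% of genes left out, the homologous recombination and Fanconi anemia list had a median of 0.13 in place of 0.26 and was not called (camera adjusted p = 0.0506), and the polycomb and DNA methylation list had a median of 0.16 (camera adjusted p = 0.0421).

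The list of G1 cyclins, CDK inhibitors and E2F genes was not called in STIC (camera of limma, adjusted p = 0.0600), although CCNE1, E2F3 (0.96) and CDK2 (0.69) rose and CCND2 (-1.46) fell among its 19 measured genes (4 rose and 1 fell adjusted over the list alone).

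Of 33 measured genes of motile cilia, 28 fell in STIC and 0 rose (32 fell adjusted over the list alone). CDHR3, a cadherin-related protein of ciliated cells, fell by 3.05. RSPH1, a radial spoke protein, stood at -2.48 and FOXJ1, a transcription factor of ciliated cells, at -1.17. The mean level of the cilia list went from 5.74 ± 0.63 to 4.37 ± 0.18 (SD, n = 6), lower in 6 of 6 patients (camera adjusted p = 5.17e-32; adjusted p = 0.0788 with an estimated correlation). Among 19 oviduct secretory and Mullerian genes, CRISP3, OVGP1 (the oviduct glycoprotein, -1.94) and CD44 fell and KRT7 rose (5 fell and 4 rose adjusted over the list alone). This list was not called, with a median of -0.07 (camera adjusted p = 0.508). Among 12 sex steroid receptors and targets, 3 fell and 0 rose (7 fell adjusted over the list alone), namely SLC7A2 at -1.32, TFF3 at -1.10 and the progesterone receptor gene PGR at -0.72. The median of that list was -0.37 (camera adjusted p = 0.00183; adjusted p = 0.182 with an estimated correlation).

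Of 7 MHC class II presentation genes, 4 fell in STIC and 0 rose (7 fell adjusted over the list alone), led by the invariant chain gene CD74 at -1.49 and HLA-DRA at -1.36. Their median was -0.93, lower in 6 of 6 patients by list mean (camera adjusted p = 2.39e-05; adjusted p = 0.120 with an estimated correlation). Macrophages, which express these genes, had a list median of -0.27 with 0 of 15 markers called (camera adjusted p = 0.0630). Of 23 interferon response genes, IFI44 and HERC5 rose (8 rose adjusted over the list alone), with a median of 0.34 (camera adjusted p = 4.41e-05; adjusted p = 0.220 with an estimated correlation). Without replicate 3 this median was 0.62. The levels of IFI44 and HERC5 in normal oviduct, 3.00 and 3.31, lay below 3.69, so their increases are lower bounds. Of 19 epithelial junction and keratin genes, KRT7 and SPINT2 rose (5 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.00699; adjusted p = 0.259 with an estimated correlation, and 0.133 without replicate 6), or 0.16 after quantile normalization. Of 18 immediate early and heat shock genes, EGR3 fell (4 fell adjusted over the list alone), with a median of -0.35 (camera adjusted p = 0.00183; adjusted p = 0.394 with an estimated correlation).

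Markers of other cell types were not called in STIC against normal oviduct. The list medians were -0.03 for fibroblast and collagen matrix, -0.01 for smooth muscle, -0.10 for endothelium, 0.01 for mesothelium, -0.04 for adipocyte, -0.12 for T and NK cell and -0.20 for B and plasma cell, with 0 members called in each and 0 adjusted over the list alone. Neither were the lists of MHC class I presentation (median -0.08), hypoxia (-0.17), glycolysis (0.10; GPI rose), oxidative phosphorylation (0.14), ribosomal protein (0.04), Wnt targets and antagonists (-0.05; APCDD1 fell), oncofetal (0.23; PEG10 rose), cancer-testis (-0.04) and EMT transcription factors and mesenchymal adhesion (-0.15; CDH2 rose and CDH11 fell). Adjusted over the list alone, 2 MHC class I genes, 1 glycolysis, 3 Wnt, 2 oncofetal and 2 EMT genes passed. Camera adjusted p of these lists lay between 0.138 and 0.937. The mean and the median had opposite signs for the fibroblast and mesothelium lists. In the panel, the differences of CDKN2A (0.19, limma adjusted p = 0.679), EZH2 (0.43, 0.0890), PAX8 (0.35, 0.141), PAX2 (-0.84, 0.0837), WT1 (0.09, 0.855), ESR1 (0.16, 0.749) and COL1A1 (0.21, 0.749) did not pass.

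In limma's test of STIC against normal oviduct, 944 of 14223 genes were called, 515 higher and 429 lower, and 239 of them changed at least 2-fold, 79 higher and 160 lower. Of the called genes, 726 had the same sign in all 6 patients. Camera called 12 of 31 lists, 7 higher and 5 lower, of which 0 were called with an estimated correlation, and 11 lists reached the smallest exact sign-flip p, 0.03125 (exact adjusted p = 0.0881). Fry called 11 lists. Without the patient block limma called 508 genes, 218 higher and 290 lower, and a fit to the 12 arrays of these 2 tissues called 582, without DNMT3A, PGR and SLC7A2 (limma adjusted p = 0.0534 to 0.0975). Without replicates 1, 2, 4 or 6 it called 568, 374, 458 or 608, and leaving out some patients ended the calls of CCNE1, CD74, DNMT3A, FIGN, GINS1, HLA-DRA, PGR, RBBP4 or SCGB1A1.

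**Figure D1:**
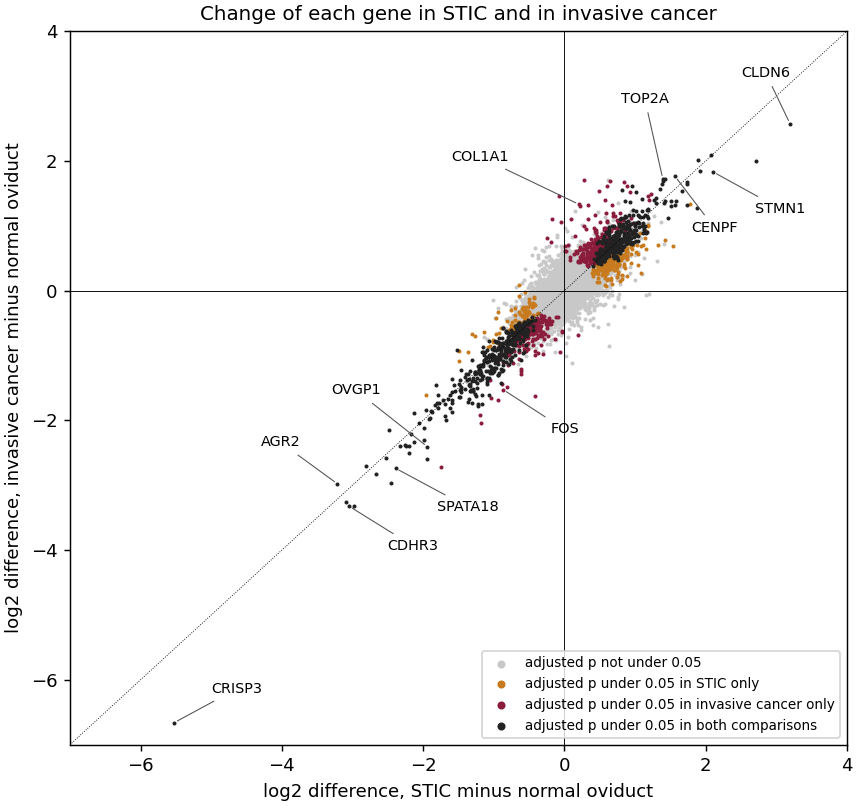
Log2 differences from normal oviduct in STIC (x axis) and in invasive serous cancer (y axis), 1 point per gene, coloured by the comparison in which limma called it, which does not test whether a gene called in 1 comparison differs from the other. CRISP3 lies farthest out, at -5.52 and -6.66, and 0 genes were called in opposite directions.

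The comparison of invasive serous cancer with normal oviduct asked which genes differ between the invasive tumour and the normal tube of the same patient. Of 29 mitosis genes 23 rose in invasive cancer, and of 33 motile cilia genes 30 fell, and camera called both lists with an estimated correlation as well (adjusted p = 0.0482). Of 23 fibroblast and collagen matrix genes 10 rose, and of 18 immediate early and heat shock genes 9 fell, but these lists lost their calls with an estimated correlation (adjusted p = 0.201 and 0.103). CRISP3 fell by 6.66 ± 0.34 (SE), at least 101-fold since its level in invasive cancer was not shown to be above background, to 3.40 ± 0.36 (SD, n = 6; limma adjusted p = 3.11e-08). STMN1 rose by 1.83 ± 0.16 (SE), 3.55-fold, to 6.99 ± 0.59 (SD, n = 6; limma adjusted p = 1.01e-05), and by 0.93 averaged over all its features. CLDN6 rose by 2.57 ± 0.61 (SE), 5.96-fold (limma adjusted p = 0.0179).

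The other named increases in invasive cancer were H2AC21 at 2.09, CCZ1P-OR7E38P at 2.01, H4C13 at 1.85, CENPF at 1.76, TOP2A at 1.72 and TPX2 at 1.72, of which the first 3 have near-identical copies and are uncertain. The named decreases after CRISP3 were CDHR3 at -3.32, FYB2 at -3.31, SCGB1A1 at -3.25, AGR2 at -2.98, CFAP65 at -2.97, MS4A8 at -2.83 and SPATA18 at -2.74. CFAP65 is a protein of cilia and flagella, and averaged over all its features it stood at -1.81. The levels of CRISP3, FYB2, AGR2 and SPATA18 in invasive cancer lay between 3.11 and 3.63, below the lower quartile of every array (3.69), so their decreases are lower bounds and have no order. The same holds for the decreases of CIMAP3 and PGR in invasive cancer, and for the increases of H4C13, CENPF and TOP2A, whose levels in normal oviduct lay between 3.49 and 3.59.

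Of 29 mitosis genes, 23 rose in invasive cancer and 0 fell (26 rose adjusted over the list alone), with CENPF, the topoisomerase gene TOP2A and MKI67 (1.35) among them. The mean level of the mitosis list was 4.85 ± 0.46 (SD, n = 6), higher than in normal oviduct in 6 of 6 patients (camera adjusted p = 5.90e-27). Of 26 DNA replication genes, 10 rose and 0 fell (14 rose adjusted over the list alone), with the ribonucleotide reductase gene RRM2 at 1.46 and GINS1 at 1.14. Of 21 homologous recombination and Fanconi anemia genes, 6 rose and 0 fell (9 rose adjusted over the list alone), among them RAD54L at 0.91 and FANCI, whose level lay below 3.69 in both tissues. Among 16 polycomb and DNA methylation genes, EZH2, the polycomb methyltransferase (0.72), and HELLS, below 3.69 in both tissues, rose (7 rose adjusted over the list alone). Among 20 serous carcinoma reference genes, STMN1, SPP1 (1.71), CCNE1 (1.16), LAMC1 (1.13) and EZH2 rose and 0 fell (8 rose adjusted over the list alone). Of 33 motile cilia genes, 30 fell and 0 rose (33 fell adjusted over the list alone), with CDHR3, CIMAP3 at -2.60 and FOXJ1 at -1.15. The mean level of the cilia list was 4.21 ± 0.20 (SD, n = 6), lower in 6 of 6 patients (camera adjusted p = 1.42e-38). These 6 lists were called by camera, and each held with an estimated correlation (adjusted p = 0.0482). With the dimmest 33.3% of genes left out, the homologous recombination and Fanconi anemia list was not called, with a median of 0.09 in place of 0.26 (camera adjusted p = 0.157).

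Of 23 measured fibroblast and collagen matrix genes, 10 rose in invasive cancer against normal oviduct and 0 fell (13 rose adjusted over the list alone). SPARC rose by 1.62 (limma adjusted p = 0.00221), VCAN, the proteoglycan versican, by 1.54 (limma adjusted p = 2.28e-04) and the collagen gene COL1A1 by 1.33 (limma adjusted p = 0.00957). The mean level of the fibroblast list went from 4.94 ± 0.17 to 5.58 ± 0.44 (SD, n = 6), higher in 6 of 6 patients (camera adjusted p = 5.16e-09; adjusted p = 0.201 with an estimated correlation). Beside it, the macrophage and myeloid list had a median of 0.16, smooth muscle 0.10 and endothelium 0.00, each with 0 members called. Of 18 immediate early and heat shock genes, 9 fell and 0 rose (12 fell adjusted over the list alone), with the transcription factor genes FOS at -1.53 and EGR1 at -1.49. Without replicate 5 they stood at -0.97 and -0.93. The level of this list went from 7.34 ± 0.19 to 6.64 ± 0.62 (SD, n = 6), lower in 5 of 6 patients (camera adjusted p = 1.61e-08; adjusted p = 0.103 with an estimated correlation).

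Of 19 G1 cyclins, CDK inhibitors and E2F genes, 4 rose in invasive cancer, including CCNE1 and E2F3 (0.87), and CCND2 fell (8 rose and 1 fell adjusted over the list alone). Their median was 0.27 (camera adjusted p = 0.00553; adjusted p = 0.103 with an estimated correlation, and 0.0509 without the dimmest 33.3% of genes). Among 19 oviduct secretory and Mullerian genes, CRISP3, OVGP1 (-2.41), CD44 and the Mullerian transcription factor gene PAX2 (-0.96) fell and 0 rose (4 fell adjusted over the list alone). The median of this list was -0.10 (camera adjusted p = 0.0279; adjusted p = 0.216 with an estimated correlation, 0.0509 without the dimmest 33.3% of genes, and up to 0.143 without replicate 3 or 5). It was -0.15 after quantile normalization and -0.19 without replicate 2. Among 12 sex steroid receptors and targets, SLC7A2 (-1.55), TFF3 (-1.34) and PGR (-0.83) fell (4 fell adjusted over the list alone), with a median of -0.29 (camera adjusted p = 1.16e-04; adjusted p = 0.103 with an estimated correlation).

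MHC class II presentation genes had a median of -0.57 in invasive cancer, with CIITA, their transactivator, as the 1 member of 7 that fell (3 fell adjusted over the list alone; camera adjusted p = 0.00350; adjusted p = 0.244 with an estimated correlation). The interferon response list had a median of 0.35, with CXCL9 as the 1 member that rose (1 adjusted over the list alone; camera adjusted p = 8.74e-04; adjusted p = 0.264 with an estimated correlation). Without the dimmest 33.3% of genes it had a median of 0.23 and was not called (camera adjusted p = 0.0866). The level of CXCL9 in normal oviduct, 3.16, lay below 3.69, so its increase is a lower bound. Of the epithelial list, SPINT2 rose (3 rose and 1 fell adjusted over the list alone), with a median of 0.20 (camera adjusted p = 0.0415; adjusted p = 0.355 with an estimated correlation, and up to 0.291 without replicates 1, 2 or 6). This list was also not called after quantile normalization, without the dimmest genes and without the patient block (camera adjusted p = 0.110, 0.0509 and 0.0503). Of 16 oxidative phosphorylation genes, CYC1 rose (1 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0207; adjusted p = 0.301 with an estimated correlation, and up to 0.253 without replicate 1 or 6), and of 0.11 without replicate 1.

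The glycolysis list was not called in invasive cancer (median 0.04, camera adjusted p = 0.0564), although GPI (0.89), ENO1 (0.76) and PKM rose among its 14 genes (3 adjusted over the list alone). Nor was the hypoxia list (median 0.16, camera adjusted p = 0.574), in which KDM3A (0.58) and VEGFA (0.56) rose and PFKFB3 fell (3 rose and 1 fell adjusted over the list alone). SFRP1 fell in the Wnt list (2 fell adjusted over the list alone), CTCFL rose in the cancer-testis list (1 adjusted over the list alone), and in the oncofetal list 0 members were called (3 rose adjusted over the list alone). In the MHC class I list 2 members fell adjusted over the list alone. The remaining lists, of EMT genes, mesothelium, adipocyte, T and NK cell, B and plasma cell and ribosomal proteins, had 0 members called by either adjustment. Camera adjusted p of the lists in the last 3 sentences lay between 0.117 and 0.992. The mean and the median of the cancer-testis list had opposite signs, and the adipocyte list's test pointed lower against a mean and median above 0. In the panel, the differences of PAX8 (0.30, limma adjusted p = 0.230), CDKN2A (0.36, 0.393), WT1 (-0.00, 0.999) and ESR1 (0.02, 0.976) did not pass.

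In limma's test of invasive cancer against normal oviduct, 1063 of 14223 genes were called, 569 higher and 494 lower, and 295 changed at least 2-fold, 103 higher and 192 lower. Of the called genes, 858 had the same sign in all 6 patients. Camera called 16 of 31 lists, 10 higher and 6 lower, and 6 with an estimated correlation, and 13 lists reached the smallest exact sign-flip p, 0.03125 (exact adjusted p = 0.0745). Fry called 13 lists. Without the patient block limma called 648 genes, 291 higher and 357 lower, and a fit to the 12 arrays of these 2 tissues called 684, without EGR1, FOS, KDM3A, PAX2 and VEGFA (limma adjusted p = 0.0647 to 0.0956). Without replicates 1, 2, 4 or 6 it called 605, 618, 637 or 657, and leaving out some patients ended the calls of CLDN6, COL1A1, EGR1, ENO1, FOS, FOXJ1, GINS1, KDM3A, PAX2, RRM2 or VEGFA.

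**Figure D2:**
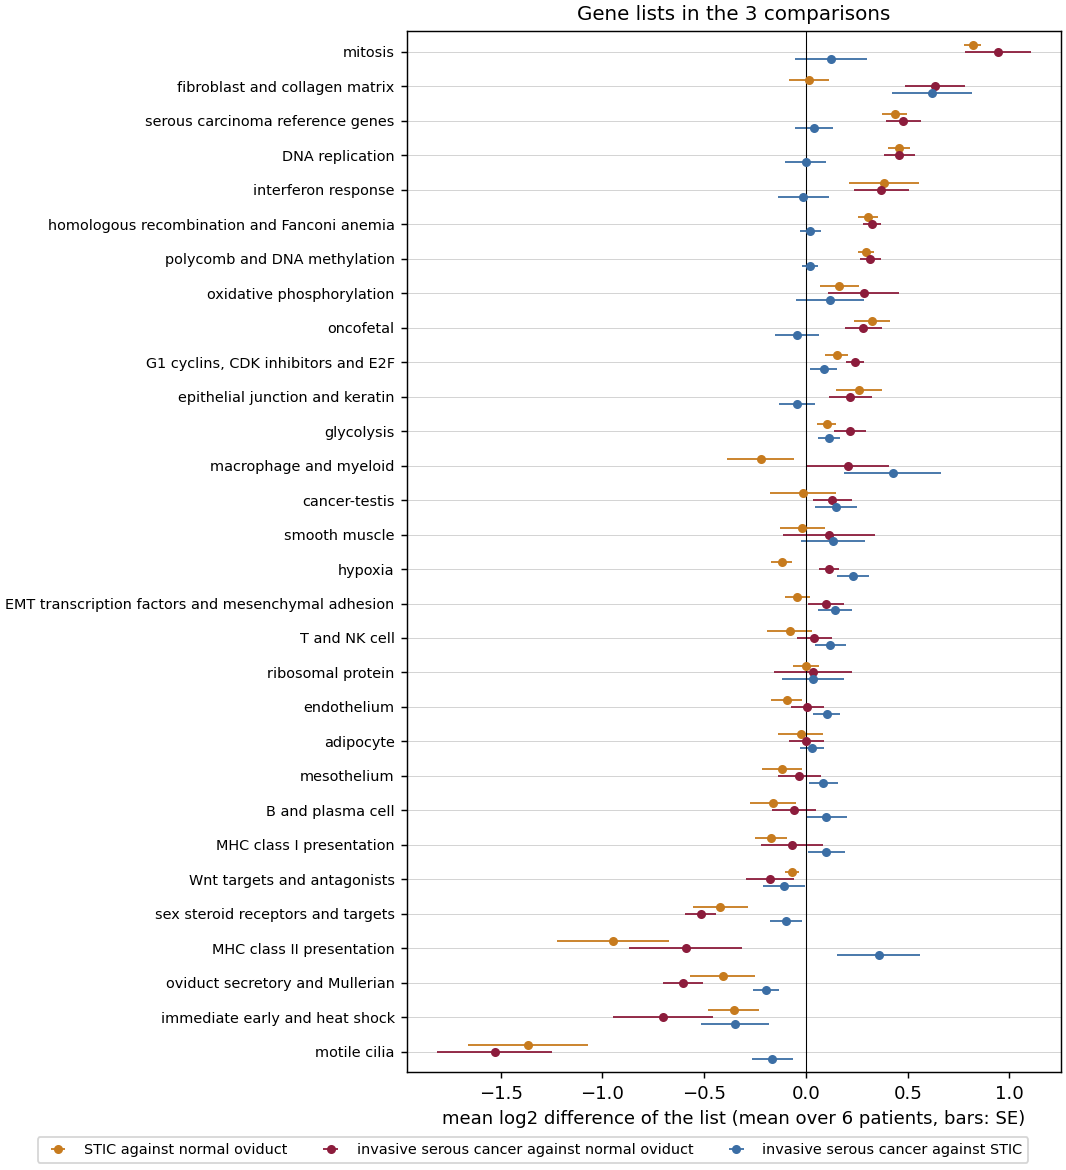
Mean log2 difference of each of 30 gene lists in the 3 comparisons, as the mean over 6 patients with bars of 1 SE. The mitosis list lies to the right and the motile cilia list to the left in both comparisons with normal oviduct.

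Both comparisons with normal oviduct called 323 genes higher and 340 lower, and 0 genes in opposite directions. Independent lists of these sizes would share 20.6 and 14.9 genes. Simulated unchanged tissues shared at most 0, but with at most 1 gene called in them this sets no scale for the overlap. At an unadjusted p under 0.05 the simulated tissues also had genes. There, 1096 genes were shared higher and 892 lower in the data, against 181.6 and 124.1 for independent lists. The 10 simulations with shared normal arrays gave 83.1 and 83.7 on average, against 9.06 and 9.27 for independent lists of their sizes. As a multiple of independent lists the real overlap was not larger. The largest multiple possible falls as lists grow, and the real lists were longer, so the multiples cannot be compared. The shared counts themselves lay above the highest of these simulations, 94 and 101. No simulated gene was changed in either tissue, so how much of the overlap is shared change was not measured. Across the 14223 genes, which are not independent replicates, the differences in STIC and in invasive cancer correlated at r = 0.863, where simulated unchanged tissues sharing the normal arrays gave 0.50 on average. The covariance was 0.115 against 0.0192 simulated, a difference of 0.0960. Beyond the patient's level, the simulations drew independent noise for each array, while STIC and invasive arrays of a patient shared deviations (median correlation 0.365). The simulated counts, r and covariance may therefore be too low. With the patients split 3 and 3 so that no array was shared, r had a median of 0.540 over 20 splits, from 0.360 to 0.596. Each side then also held fewer patients, which lowers r. The covariance over these splits had a median of 0.0923, from 0.0686 to 0.108.

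**Figure D3:**
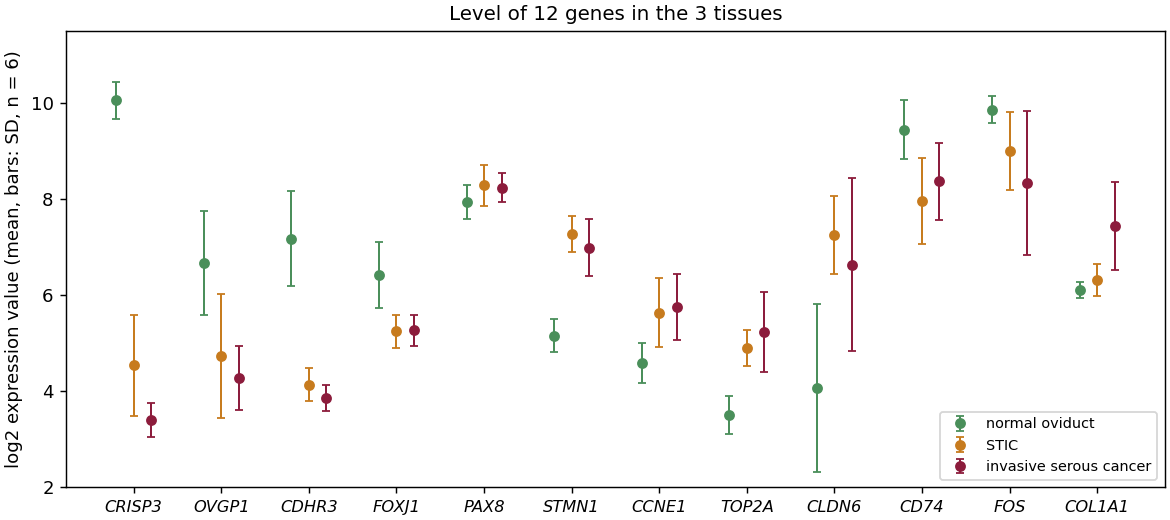
Log2 levels of 12 genes in the 3 tissues, as the mean with bars of 1 SD (n = 6). CRISP3 went from 10.06 in normal oviduct to 4.53 in STIC and 3.40 in invasive cancer.

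The comparison of invasive serous cancer with STIC asked which genes differ between the invasive tumour and the lesion of the same patient. Camera called the fibroblast and collagen matrix list higher in invasive cancer, but not with an estimated correlation (adjusted p = 0.121), and 0 single genes passed the test. The level of the fibroblast list went from 4.96 ± 0.16 to 5.58 ± 0.44 (SD, n = 6), higher in 5 of 6 patients (exact sign-flip p = 0.0625, adjusted p = 0.388). Its median difference was 0.60 (camera adjusted p = 1.52e-25; fry adjusted p = 0.0639), with 12 of 23 members higher and 0 lower adjusted over the list alone. COL1A1 of the panel was higher by 1.12 ± 0.29 (SE) without passing (limma adjusted p = 0.716).

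Limma called 0 of 14223 genes between invasive cancer and STIC, with a smallest adjusted p of 0.164. At an unadjusted p under 0.05 there were 558 genes, where chance would give 711. Compared alone, the 2 tissues gave 757 such genes, and array weights 859, with 0 called in each. The other fits to all 14223 genes gave 332 (no patient block) to 683 (without replicate 5). The main fit shares a single spread, while same-patient deviations correlated at a median of 0.365 for these 2 tissues, against 0.102 and 0.0948 with normal oviduct. Its spread may be too wide here and too narrow against normal oviduct. The 558 is thus no sign of fewer differences than chance. Genes with the same sign in all 6 patients made up 3.19% of genes, where chance gives 3.125%. With the patient as a random block limma called 3 genes, COL3A1, VCAN and OR6C3, and without replicate 5 it called COL3A1 and VCAN. These genes were chosen after their values were seen: COL3A1, a fibrillar collagen gene, was higher by 1.52 (95% interval 0.98 to 2.07, limma adjusted p = 0.164), and VCAN by 1.05 (limma adjusted p = 0.206). In the fit with the shared spread, the median 95% interval of a gene's difference reached 0.34 to either side on the log2 scale. For a typical gene, smaller differences could not be told from 0 in that fit. This interval is not adjusted for the 14223 genes tested, and far larger differences also failed to pass, such as COL3A1 at 1.52. In the simulated data 22.4% of changes of 0.50 were recovered in this comparison. The 0 calls therefore do not exclude differences well above 0.34.

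Camera called 10 of 31 lists between invasive cancer and STIC, 7 higher and 3 lower, of which 0 were called with an estimated correlation (lowest adjusted p = 0.121) and 0 by fry. Besides the fibroblast list, the lists called higher were macrophage and myeloid (median 0.45, with TYROBP and C1QA higher adjusted over the list alone), MHC class II presentation (0.42), EMT transcription factors and mesenchymal adhesion (0.27, with CDH11 higher adjusted over the list alone), hypoxia (0.22), mitosis (0.13) and T and NK cell (0.12). With an estimated correlation, adjusted p = 0.286, 0.596, 0.286, 0.121, 0.661 and 0.661 in this order. For hypoxia that correlation was 0.0073, below the preset 0.01, so its lost call does not show correlated members. The lists called lower were immediate early and heat shock (-0.31), motile cilia (-0.20) and oviduct secretory and Mullerian (-0.10, with CRISP3 and WFDC2 lower adjusted over the list alone). With an estimated correlation, adjusted p = 0.286, 0.661 and 0.273 in this order. Hypoxia, higher in 6 of 6 patients, and oviduct secretory, lower in 6 of 6, reached the smallest exact sign-flip p, 0.03125 (exact adjusted p = 0.388). Endothelium markers had a median of 0.13 and smooth muscle markers 0.07 beside the fibroblast and macrophage lists (camera adjusted p = 0.0505 and 0.212).

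In this comparison, 4 of the other lists had members passing adjusted over the list alone: PECAM1 of endothelium, CXCL9 of interferon response, RPS14 of ribosomal protein, and SPP1 (higher) and WFDC2 (lower) of the serous carcinoma list. Camera adjusted p of the 21 lists not called lay between 0.0505 and 0.868, and the median, the mean and the test differed in sign for DNA replication, ribosomal protein, oncofetal and serous carcinoma genes. Panel genes other than COL1A1 differed by -0.47 (OVGP1) to 0.29 (EZH2), and STMN1 by -0.28, each at a limma adjusted p of 0.999. Without replicate 1, camera no longer called EMT, MHC class II, T and NK cell, hypoxia, mitosis and motile cilia, with adjusted p from 0.0606 to 0.918. EMT was also lost without replicate 2, 3 or 4, MHC class II without 3, T and NK cell without 2, 3 or 6, and mitosis without 5. Without replicate 1 the medians were 0.26 for macrophage and myeloid, 0.20 for MHC class II, 0.17 for EMT, 0.11 for hypoxia, 0.03 for mitosis and -0.09 for motile cilia. Without replicate 2 they were 0.17 for EMT, 0.04 for T and NK cell and -0.12 for motile cilia. Mitosis was at 0.19 without replicate 3 and at 0.26 without replicate 4, oviduct secretory at -0.05 without replicate 3 and -0.15 without 5, and immediate early at -0.18 without 5. Without the dimmest 33.3% of genes, T and NK cell had a median of 0.08 and was not called (camera adjusted p = 0.334).

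**Figure D4:**
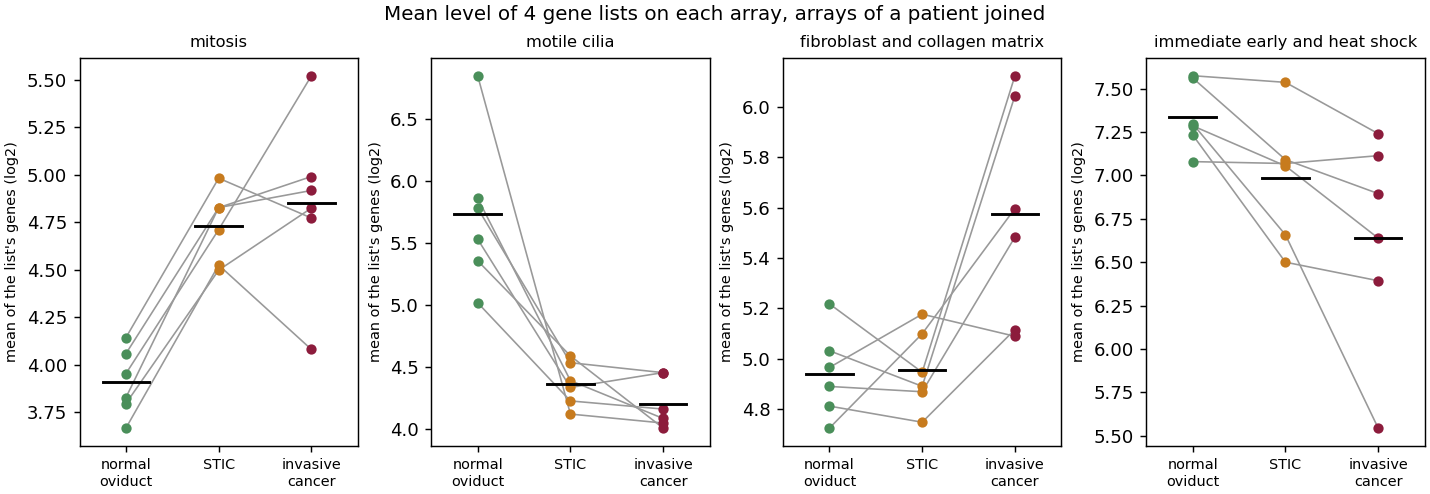
Mean log2 level of 4 gene lists (y axis) on each array of the 3 tissues (x axis), with 1 point per array, grey lines joining the arrays of a patient and black bars at the mean of each tissue (n = 6). The mitosis list went from 3.91 in normal oviduct to 4.73 in STIC and 4.85 in invasive cancer, and the fibroblast list from 4.94 to 4.96 and 5.58.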

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

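The comparisons with other splits of the arrays were chosen only after the results were seen, while the tests on replicate 5 were set before their results were known. Each group of 6 arrays was searched for 1 array whose gap to its nearest neighbour was, as a share of the group's range, above Dixon's 95% critical value for 6 values. This was so in 18 of 276 groups (6.52%), where chance gives about 1 in 20.

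Among gene lists in normal oviduct, 1 array stood low for oviduct secretory and Mullerian genes (gap 0.755 of the range, 6.41 against 6.64 to 6.71 on the others) and 1 for oxidative phosphorylation (0.696, 5.25 against 5.53 to 5.66). In invasive cancer 1 array stood low for Wnt targets and antagonists (0.672, 4.67 against 5.05 to 5.24). Among genes in normal oviduct, 1 array stood high for FOXJ1 (0.687, 7.75 against 5.91 to 6.48), 1 for MT1G (0.640, 6.26 against 4.08 to 4.86) and 1 for SLC7A2 (0.714, 6.86 against 4.78 to 5.38). In STIC 1 array stood high for HLA-DRA (0.701, 7.89 against 5.79 to 6.42) and 1 for SCGB1A1 (0.701, 7.94 against 4.98 to 5.87). In invasive cancer 1 array stood low for CDKN2A (0.706, 4.13 against 5.19 to 5.64), 1 for KDM3A (0.642, 4.27 against 4.95 to 5.33), 1 for SSB (0.699, 3.96 against 7.47 to 8.98) and 1 for WT1 (0.690, 5.77 against 6.80 to 7.26). In invasive cancer 1 array stood high for CRISP3 (0.668, 4.10 against 3.10 to 3.43) and 1 for SPP1 (0.684, 8.97 against 6.55 to 7.31).

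The STIC and invasive arrays of replicate 5 stood apart as whole arrays. Their median correlation with the other arrays was 0.870 in STIC (gap 0.864) and 0.862 in invasive cancer (gap 0.736), and the invasive array also had the smallest standard deviation, 1.496 (gap 0.632), and range between quartiles, 1.53 (gap 0.661). Over the genes called without it, the slope of a patient's differences from normal oviduct on those of the other patients averaged 0.558 for replicate 5 and 0.573 to 1.31 for the others. After quantile normalization it was 0.623 against 0.582 to 1.26, inside the range of the others, as predicted for a compressed range of values. This test could hardly fail, because the slope had lain only just below that range before. The slopes also rested on unlike gene sets, 1283 and 1200 genes for replicate 5 and 374 to 793 for the others. Limma's array weight was lowest for the normal oviduct array of replicate 5 (0.329), below its STIC (0.653) and invasive (1.05) arrays. A compressed range on the STIC and invasive arrays is thus neither shown nor excluded. For normal oviduct cells on these arrays, slopes of genes that rose and that fell differed by -0.475. This lay inside the range of the other patients, -0.826 to 0.190, whose low end came from replicate 4. For genes that rose, replicate 5 had slopes of 0.206 in STIC and 0.4004 in invasive cancer, below the other patients (lowest 0.582 and 0.512). For genes that fell it had 0.769 and 0.786, inside the others' ranges (0.6095 to 1.68 and 0.565 to 1.599). Such cells would shrink decreases too, so these values argue against them as the whole cause of the small increases. A smaller share of such cells stays open. No biological explanation was tested.

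Features outside the gene tests also changed. Limma called 81 of 5171 features that name no gene here in STIC against normal oviduct, 61 higher and 20 lower, and 84 in invasive cancer, 56 higher and 28 lower. Of 2384 features naming several genes, it called 69 in STIC, 38 higher and 31 lower, and 81 in invasive cancer, 40 higher and 41 lower. Between invasive cancer and STIC it called 0 of either kind.

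For each comparison, 100 splits of the 12 arrays into groups of 6 were fitted, the real one included. The 6 arrays of the third tissue stayed in every fit. For genes called, only the real split reached the real count in STIC against normal oviduct (1 of 100 splits as large, 944 real, highest other 270) and in invasive cancer against normal oviduct (1 of 100, 1063 real, highest other 394). For genes changed at least 2-fold this was so in both as well (1 of 100 each, 239 real with a highest other of 86, and 295 real with a highest other of 114). For the lists called by camera with its preset correlation, chance cannot be excluded in any comparison. In STIC against normal oviduct 13 of 100 splits called as many lists (12 real, highest other 15), in invasive cancer against normal oviduct 5 of 100 (16 real, highest other 19) and in invasive cancer against STIC 10 of 100 (10 real, highest other 16). Between invasive cancer and STIC the real counts of genes called and of genes changed at least 2-fold were 0, so all 100 splits were as large by construction (highest other 2), and this says nothing about chance. Among the 32 splits that part every patient's pair, the highest other count of genes was 270 in STIC and 7 in invasive cancer against normal oviduct. Only these 32 keep the pairing, so a real split that is the largest has a share of 1 in 32 at best. In the other splits a tissue difference adds to the spread and lowers the counts, so they set no stricter limit on chance. In these 32, as many lists as the real split were called in 6, 4 and 3 splits, in the order of the lists above.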

How the results depend on the processing

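All alternatives were planned, none was added after the results were seen, and all were run. Of 418 values of called gene lists under alternatives, 353 kept direction and call, 64 lost the call and 1 turned. These values cover camera with an estimated correlation, quantile normalization, centring, the dimmest genes left out, no patient block and each patient left out. Fry is not in this tally, and the remaining alternatives were applied to genes only. Of 1581 values of named genes, 1474 kept both, 83 lost a call, 1 gained one and 23 turned, and 70 of 106 gene differences kept both under every alternative.

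Without the patient block, limma called 508 genes in STIC and 648 in invasive cancer against normal oviduct, in place of 944 and 1063, and the share called higher went from 54.6% to 42.9% in STIC and from 53.5% to 44.9% in invasive cancer. The calls of CCNE1, DNMT3A, GINS1, HLA-DRA, PGR, RAD51AP1 and SSB in STIC, of CLDN6, EGR1, ENO1, FOS, GPI, KDM3A, PAX2 and VEGFA in invasive cancer and of the epithelial list in invasive cancer were lost without the block, and no other call of a named gene or called list changed. With only the 12 arrays of the 2 tissues, 582 and 684 genes were called, and the calls of DNMT3A, PGR and SLC7A2 in STIC and of EGR1, FOS, KDM3A, PAX2 and VEGFA in invasive cancer were lost (limma adjusted p = 0.0534 to 0.0975). Array weights ended the calls of RBBP4 and HLA-DRA in STIC (limma adjusted p = 0.121 and 0.0521), a random patient block those of SSB in STIC and VEGFA in invasive cancer (0.116 and 0.0524), and trended and robust variance that of PAX2 in invasive cancer (0.0509). A random patient block called 3 genes, all at least 2-fold, in invasive cancer against STIC, where the fixed block called 0.

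Leaving out 1 patient, which also leaves fewer arrays, gave 374 to 1283 genes called in STIC (159 to 295 at least 2-fold), 605 to 1200 in invasive cancer and 0 to 2 between invasive cancer and STIC (0 to 2 at least 2-fold). The highest counts against normal oviduct came without replicate 5. With the dimmest 33.3% of genes left out, 192 in place of 295 genes changed at least 2-fold in invasive cancer, since fewer genes were tested. Lists called by camera with an estimated correlation numbered 0 in STIC, 6 in invasive cancer and 0 between invasive cancer and STIC, and fry called 11, 13 and 0. Between invasive cancer and STIC, leaving out 1 patient gave 6 to 10 lists called by camera. Between invasive cancer and STIC, 4 lists reached the smallest exact p after quantile normalization and 1 without the dimmest genes, in place of 2. The correlation of the changes in STIC and invasive cancer fell to a median of 0.540 with no array shared. Where no reason is given, the cause was not tested.

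Calls lost in single fits that left out 1 patient had limma adjusted p of 0.05003 to 0.157 in STIC (CCNE1, CD74, DNMT3A, FIGN, GINS1, HLA-DRA, PGR, RBBP4, SCGB1A1) and 0.0510 to 0.172 in invasive cancer (CLDN6, COL1A1, EGR1, ENO1, FOS, FOXJ1, GINS1, KDM3A, PAX2, RRM2, VEGFA). PAX2 was called in STIC without replicate 4 (-1.12, limma adjusted p = 0.0214). Apart from the mitosis list between invasive cancer and STIC, directions that turned were of small gene differences that had not passed. With 1 patient left out, WT1 ranged from -0.11 to 0.17 in STIC and -0.10 to 0.22 in invasive cancer against normal oviduct, and ESR1 from -0.15 to 0.17 in invasive cancer. WT1 in invasive cancer was 0.0109 after centring. Between invasive cancer and STIC the ranges were -0.0416 to 0.307 for CDKN2A, -0.0710 to 0.221 for CCNE1, -0.215 to 0.314 for MKI67, -0.363 to 0.0383 for PAX2, -0.0931 to 0.114 for FOXJ1, -0.229 to 0.0513 for WT1, -0.281 to 0.0538 for ESR1 and -0.209 to 0.0364 for PGR. With array weights MKI67 was -0.0427 and FOXJ1 -0.0143. The mitosis list between invasive cancer and STIC ranged from 0.0258 to 0.259, and its test pointed lower without replicate 1.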

Other observations

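The gene families, and the tests on fibroblast genes outside the lists and on endothelium and smooth muscle genes, were chosen only after the results were seen. Replication-dependent histone genes, whose products package newly made DNA, were tested as a family after 2 of them were among the largest increases. Those 2, H2AC21 and H4C13, stayed in the tested family, so its p-values partly reflect that choice. Of 50 measured, 13 rose and 0 fell in STIC against normal oviduct (median 0.62; camera of limma adjusted over 9 families, p = 9.14e-13, and adjusted p = 0.0424 with an estimated correlation). In invasive cancer 21 rose and 0 fell (median 0.71; camera adjusted p = 3.73e-17, and 0.0160 with an estimated correlation). The medians kept their direction after quantile normalization (0.60 and 0.68) and after centring (0.64 and 0.72), and members of this family have near-identical copies. Between invasive cancer and STIC the median was 0.15 with 0 members called (camera adjusted p = 0.00360; adjusted p = 0.544 with an estimated correlation).

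Of 220 olfactory receptor genes, limma called 0 in STIC and 3 in invasive cancer against normal oviduct. The 13 S100 genes had a median of 0.20 between invasive cancer and STIC, with 0 called (camera adjusted p = 0.00145; adjusted p = 0.0311 with an estimated correlation), and S100A9, chosen after its values were seen, was higher by 1.29 without passing (limma adjusted p = 0.269). In the same comparison the macrophage and myeloid list had a median of 0.45, with 14 of 15 members higher (camera adjusted p = 3.14e-09; adjusted p = 0.286 with an estimated correlation).

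The fibroblast and collagen matrix list was called higher in invasive cancer than in STIC by camera (adjusted p = 1.52e-25), but not with an estimated correlation (adjusted p = 0.121), by fry (adjusted p = 0.0639) or by the exact test (adjusted p = 0.388), and 0 of its members were called over all genes. More fibroblasts among the captured invasive cells, which laser capture of regions would not remove, cannot be told apart: COL1A1 went from 6.31 ± 0.33 to 7.44 ± 0.92 (SD, n = 6), but 16 fibroblast genes in none of the lists differed by 0.172 ± 0.0824 (SE, n = 6), higher in 4 of 6 patients (exact sign-flip p = 0.156). A change within fibroblasts or tumour cells stays open as untested. Other stromal cells captured with them cannot be told apart either, because 21 endothelium and smooth muscle genes differed by 0.113 ± 0.0674 (SE, n = 6), an interval that holds both 0 and a small rise.

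The immediate early and heat shock list was called lower in invasive cancer than in normal oviduct by camera (median -0.63), but not with an estimated correlation (adjusted p = 0.103) or by the exact test (adjusted p = 0.114). Its median stayed at -0.56 without replicate 5 and at -0.62 or beyond under quantile normalization and centring, which argues against that patient or the scaling as the whole cause. Handling of the tissue before freezing could alter these genes and cannot be told apart, since the heat shock genes DNAJB1 and HSPH1 differed by -0.0966 ± 0.227 (SE, n = 6), too wide to decide. A difference between the tissues themselves stays open as untested.

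A hypothesis of recurrent gain or loss of whole chromosomes was tested by setting each of 22 chromosomes' genes against all others. With an estimated correlation the lowest adjusted p of camera was 0.0742 in STIC and 0.129 in invasive cancer, so 0 chromosomes passed. The bound set beforehand, that no chromosome passing would exclude the hypothesis, was wrong, because missing a threshold sets no limit on a shift. Chromosome 2 genes lay 0.189 above all others in STIC, higher in 6 of 6 patients, with 98 rising and 16 falling of 917. Chromosome 9 genes lay at -0.140, lower in 6 of 6 patients, with 3 rising and 31 falling of 528. Whether these shifts come from copy number could not be told from expression alone.

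A second hypothesis was a gain of the segment around CCNE1 on chromosome 19. The 60 measured genes nearest to it, without CCNE1, lay 0.241 ± 0.0642 (SE, n = 6) above all other genes in STIC and 0.180 ± 0.0433 in invasive cancer, higher in 6 of 6 patients in both, which is consistent with such a gain. Of 1239 runs of genes elsewhere, 41 (3.31%) and 84 (6.78%) lay as high, so the segment is not unusual enough to single it out in invasive cancer. Of 14 ZNF genes in the segment, 1 rose in STIC and 0 in invasive cancer, while 11 and 9 of 133 on the whole chromosome rose, so most of those lie outside it. The segment was fixed at 60 genes, and how close to it the others lie was not tested. Their number outside it therefore does not exclude a longer gain.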
